A study of Mus musculus with 6 samples.

How the data were processed

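Total RNA from C2C12 myotubes was extracted with TRIzol, amplified with a NuGEN whole-transcript kit and labelled with biotin, per the labels' protocols. The labels put 3 samples in the control group (the ATF4 form without its bZIP domain) and 3 in the ATF4 group, and give each a sample number of 1 to 3 within its group. They do not say that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. The deposited table holds 1 value per array for each of 16700 transcript clusters of the Affymetrix mouse exon array. The submitters' processing notes name GCOS, RMA and the mouse genome build mm9; versions, settings and any filter are not given in the sources used here. The deposited values are taken to be on the log2 scale, which is inferred from their range and is not stated, so each fold rests on that reading. No detection calls were used, so rows near background could not be marked, and a fold of a dim row may be understated.

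Rows were named from the platform annotation supplied with the values: 14988 rows carried 1 gene symbol, 1018 several and 694 none. Rows with several symbols or none stayed in the tests and were not assigned to a gene. Of the gene numbers, 14934 were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used for names and for which genes neighbour each other; since its build differs from mm9, no coordinates are given. The 14988 rows stood for 14852 genes, 135 of them with more than 1 row; in gene list tests such a gene was represented by the row with the highest mean over the 6 arrays. None of the genes named by the rule given below had more than 1 row. Genes chosen after their values were seen were not checked for further rows.

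Levels are means ± SD over the 3 arrays of a group. Changes are ATF4 minus control, fitted for all rows with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default moderation, no filter), two-sided, with Benjamini-Hochberg adjustment over the 16700 rows and a threshold of 0.05. Each standard error comes from that moderated fit, which had 4 residual and 6.30 prior degrees of freedom. The fit with the sample number as a block had 2 residual and 3.77 prior degrees of freedom. An exact permutation test of 3 against 3 arrays could not give a two-sided p under 0.1, so single genes were tested only with limma. The 30 gene lists were written before the data were examined; of 670 distinct genes listed, 546 had a row of their own, 41 lay only on rows with several genes (Eif4ebp1 and Cth among them) and 83 had no named row (Trim63 among them). Lists were tested with camera from limma, which asks whether a list's genes shift against all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Some genes stand in more than 1 list: Slc7a11 counts as a stress response target and a transporter, Asns as a stress response target and a synthesis enzyme, and Gadd45a as a stress response, atrophy and growth arrest gene.

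Genes were named by a rule set at the same time. It took 9 genes of interest (Atf4, Gadd45a, Asns, Trib3, Ddit3, Chac1, Cdkn1a, Fbxo32 and Trim63), and the 12 largest rises and 12 largest falls among rows past the threshold whose groups did not overlap and whose single symbol was not a clone name; 4 rows met this for falls. For each list it took up to 4 members past the threshold with the largest changes, or, where fewer than 2 passed, the 2 with the smallest p.

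Whether sample numbers pair the arrays was checked before the blocked calls were compared. The pairing comes from the sample numbers in the titles; the labels do not say what a number marks. Deviations from the group mean correlated across rows by 0.578, 0.636 and 0.782 for control and ATF4 arrays of the same number, each over the limit of 0.1 that had been set, and by -0.666 to 0.221 for arrays of different numbers. The numbers were therefore read as pairs, and the value with the sample number as a block stands beside a result where it changed the call or moved a count by over 1.5 times.

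The alternatives set in advance were the replicate block, quantile normalization again, centring on the median, scaling to one median and interquartile range, leaving out rows below the 25th percentile or the median, an intensity trend or robust estimation in eBayes, array weights, each array left out in turn, a 1.5-fold minimum, a threshold of 0.01 and 1 row per gene. For lists they also were the mean of a gene's rows, an estimated correlation, camera on ranks and fry, a rotation test of direction. Leaving out both number 3 arrays, leaving out a numbered pair under the block, cyclic loess and the block with an estimated correlation were chosen after seeing the data. The 4 rescalings named beside results are quantile normalization, centring, scaling and cyclic loess.

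The fits were tested on simulated data of 16700 rows. Each row had its mean, an added effect of each sample number and independent normal noise with the spread left by the block fit. The data were thus made as the block fit assumes, so its higher recovery was built in. Noise shared between rows, and sample number effects that differ between groups, were not simulated. Without the block, 0 of 67 rows changed 1.5-fold, 9 of 67 changed 2-fold (13.4%) and 66 of 66 changed 4-fold were called, with 0 false calls; with the block, 51 of 67 (76.1%), 67 of 67 and 66 of 66 were called, with 6 false calls. A list shifted by 0.5 was found by camera with both correlations, and 0 of the other lists were called. These list data had independent noise in each row and no effect of the sample number. They cannot show how often correlated genes give false list calls. On the real arrays the estimated correlation ran from -0.04 (mitochondrial tRNA synthetases) to 0.86 (endothelial markers). Camera with an estimated correlation also takes its p from the residual degrees of freedom, 4 without and 2 with the block. With the preset correlation this limit is absent. The cell cycle list, with an estimated correlation of 0.035, went from a camera adjusted p of 7.0e-14 to 0.0328. A call lost in that setting thus need not be owed to the correlation of its genes. Array medians ran from 5.76 to 6.00 and correlations between arrays across rows from 0.933 to 0.985. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.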

Results

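The data were transcript levels in C2C12 myotubes, the multinucleate muscle cells formed when this mouse myoblast line is made to differentiate. The myotubes had been infected with adenovirus that expressed green fluorescent protein together with one of a pair of FLAG-tagged proteins. In the ATF4 group (3 samples) the protein was ATF4, a bZIP transcription factor induced by amino acid shortage and endoplasmic reticulum stress. In the control group (3 samples) it was ATF4 without the bZIP domain, the part that binds DNA. RNA was taken 48 hours after infection and measured on Affymetrix mouse exon arrays, 1 array per sample, with 16700 rows of transcript-level values on the log2 scale. The number of arrays limits the precision, and no array of uninfected myotubes was analysed here. The comparison asks which transcripts differed when myotubes carried ATF4 that can act on genes in place of a form that cannot.

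Myotubes with ATF4 carried more mRNA of some amino acid transporters and of some targets of the integrated stress response. That response is the transcriptional program that follows phosphorylation of the translation factor eIF2. Of the measured genes, 6 of 20 transporters and 8 of 22 targets passed over all rows. Both list calls were lost when the block and an estimated correlation were used together. Of the 16700 rows, 95 were higher and 4 lower in ATF4 arrays by the limma test (adjusted p below 0.05), 99 in all. The cystine and glutamate exchanger Slc7a11 (transcript cluster 6904892) rose from 4.21 ± 0.20 to 7.49 ± 0.32 (log2, mean ± SD, n = 3 per group), a 9.67-fold rise (limma adjusted p = 1.0e-04). Asparagine synthetase, Asns (transcript cluster 6951525), rose 4.12-fold from 8.46 ± 0.54 to 10.50 ± 0.22 (limma adjusted p = 0.00646). With the sample number as a replicate block, 400 rows were higher and 194 lower, 594 in all, and 97 of the 99 rows were among them in the same direction. At an unadjusted p below 0.05 the counts were 879 rows without and 2960 with the block.

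**Figure D1:**
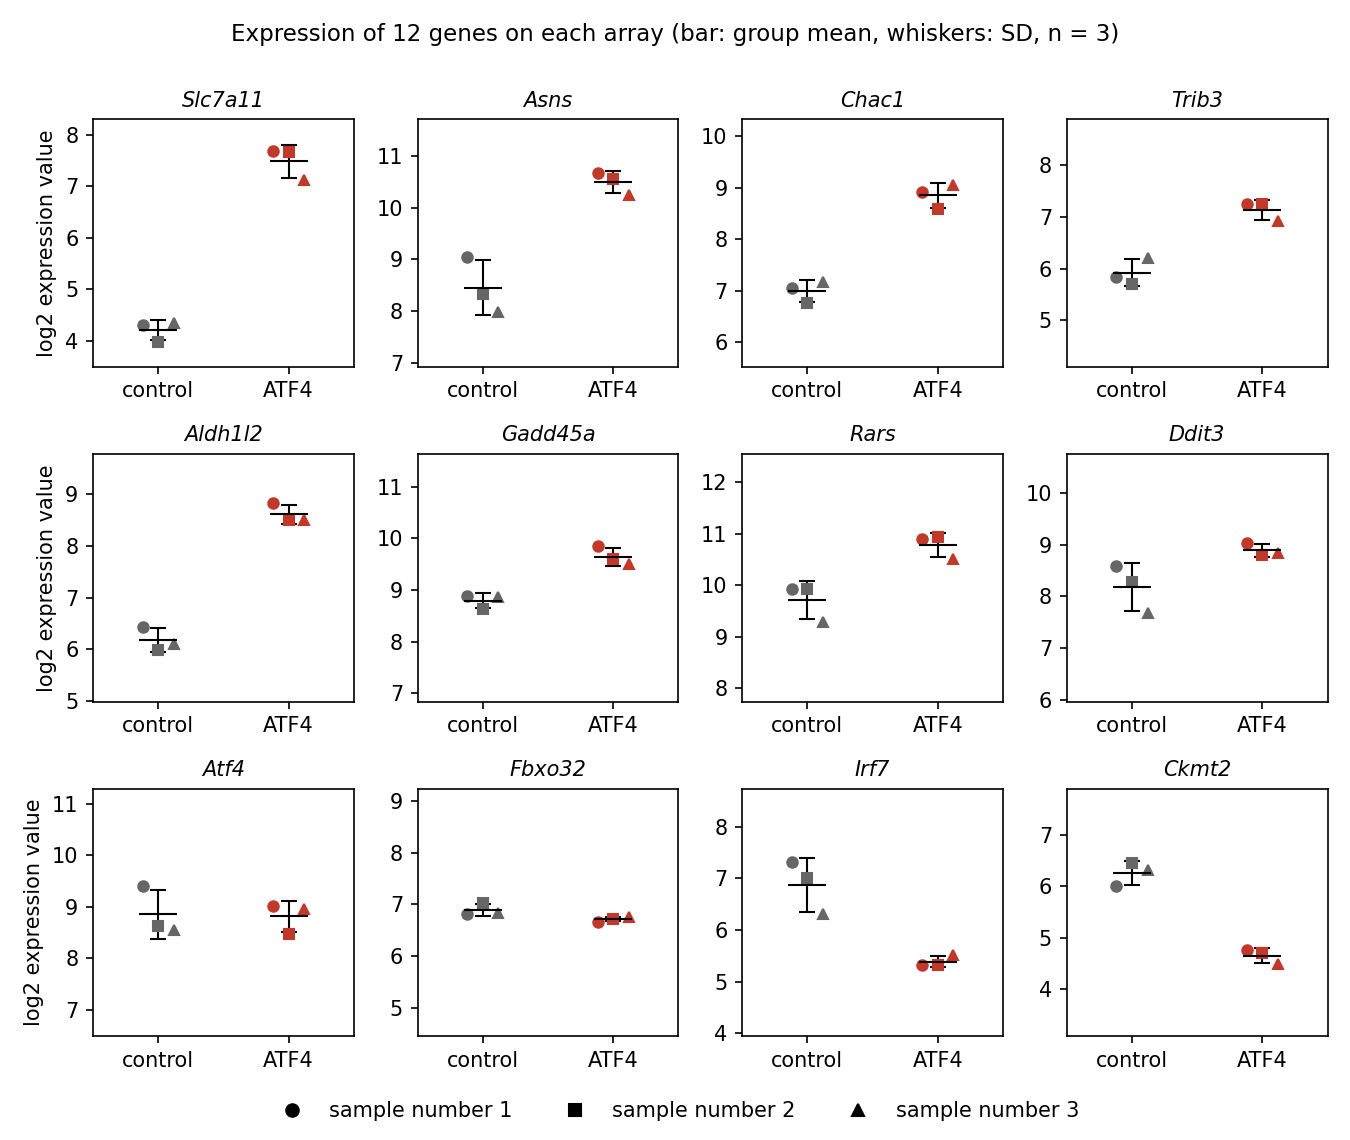
Log2 expression value (vertical axis) of 12 genes on each array, in control and ATF4 myotubes; marker shapes give the sample number, bars the group mean and whiskers the SD (n = 3). The 3 ATF4 arrays lie above the 3 control arrays for Slc7a11, Asns, Chac1, Trib3, Aldh1l2, Gadd45a, Rars and Ddit3 and below them for Fbxo32, Irf7 and Ckmt2, while the groups overlap for Atf4.

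The 12 largest rises among named rows past the threshold were not tested as a group; Dnajb9, with a larger change (2.43) than 5 of them, did not pass (limma adjusted p = 0.0790). Rgs13, a regulator of G-protein signalling, rose from 3.11 ± 0.43 to 6.97 ± 0.48 (limma adjusted p = 0.000174); its control mean lies below the 5th percentile of each array (3.40 to 3.75), so no fold is given and its rank among the rises is uncertain. Saa3, an acute-phase serum amyloid A protein, rose 13.4-fold from 4.23 ± 0.36 to 7.97 ± 0.32 (limma adjusted p = 1.0e-04). Serpinb6c, a member of the serine protease inhibitor family, rose by 3.01 on the log2 scale. P2rx3, an ATP-gated channel of sensory neurons, rose by 2.81, and Dhrs9, a short-chain dehydrogenase, rose 5.66-fold. Dsg3, a desmosomal cadherin of epithelia, rose by 2.41, the methyltransferase-like Mettl7b by 2.29, the bicarbonate transporter Slc4a10 by 2.19 and Plek, the pleckstrin of platelets and leukocytes, by 2.12. Slc7a11, Aldh1l2 and Vldlr complete these 12, all of which passed the threshold with each of the 6 arrays left out in turn. The largest rise of any row, 4.08 on the log2 scale, belonged to a row without a gene name.

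The 4 rows that fell all carried a gene name. Ckmt2, the mitochondrial creatine kinase of striated muscle, fell from 6.26 ± 0.23 to 4.65 ± 0.15, 3.04-fold (limma adjusted p = 0.00334). The insulin-like peptide gene Insl6 fell from 5.71 ± 0.45 to 4.21 ± 0.09, the interferon regulatory factor gene Irf7 from 6.88 ± 0.52 to 5.39 ± 0.11 and the costimulatory receptor gene Cd28 from 6.29 ± 0.33 to 4.95 ± 0.14, with limma adjusted p of 0.0168, 0.0283 and 0.0168. Leaving out 1 array ended 3 of these calls, with limma adjusted p up to 0.111 for Insl6 and 0.157 for Irf7 without ATF4 array 1, and up to 0.101 for Cd28 without control array 1. The same 3 calls also ended under each of 4 rescalings of the arrays (limma adjusted p from 0.0564 to 0.215), and that of Ckmt2 ended when arrays were scaled to one interquartile range (0.0543). All 4 passed with the replicate block.

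The integrated stress response targets rose as a group. Of the 25 genes listed, 22 were measured, 8 rose, none fell and 14 did not pass; 19 rose when adjusted over the list alone, and 16 with the replicate block. Their median change was 1.00 on the log2 scale (camera, adjusted p = 2.0e-47, and 0.0275 with an estimated correlation). The call was lost with both the block and an estimated correlation (camera, adjusted p = 0.212). In that setting 2 residual degrees of freedom were left and 0 of the 30 lists passed, so it cannot single out this list. Besides Slc7a11 and Asns, the lipoprotein receptor gene Vldlr rose 4.35-fold and the glutathione-degrading enzyme Chac1 3.61-fold, by 1.85 on the log2 scale (standard error 0.20; limma adjusted p = 0.00201). Trib3, a pseudokinase induced by ATF4, rose 2.33-fold (limma adjusted p = 0.0251), a call that ended when any of 4 arrays was left out, with limma adjusted p up to 0.175 without ATF4 array 1. Centring each array on its median ended the call of Asns (limma adjusted p = 0.0589), and scaling the arrays to one interquartile range that of Chac1 (0.0544). Ddit3, which encodes the stress factor CHOP, had 8.18 ± 0.47 in control and 8.90 ± 0.13 in ATF4 arrays and did not pass (limma adjusted p = 0.468, and 0.0782 with the block). Listed targets on rows with several genes were left out of these counts. The row shared by Cth and Rpl32l rose by 3.46 on the log2 scale (limma adjusted p = 3.9e-05). The row shared by Eif4ebp1 and Ccnq rose by 0.93 (limma adjusted p = 0.0491). Neither rise can be assigned to 1 gene.

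The row for Atf4 itself (transcript cluster 6831994) had 8.86 ± 0.47 in control and 8.82 ± 0.30 in ATF4 arrays, a difference of -0.04 with a standard error of 0.26 (limma adjusted p = 1). Both viral constructs carry Atf4 sequence, so this row does not check the labels.

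Some amino acid synthesis enzymes were higher in ATF4 arrays. Of 21 listed genes 14 were measured, and 4 rose while none fell and 10 did not pass (6 rose when adjusted over the list alone, 7 with the replicate block). Besides Asns, these were the serine synthesis enzyme Psph (log2 change 1.37, standard error 0.19), the branched-chain aminotransferase Bcat1 (1.28, standard error 0.23) and the proline synthesis enzyme Aldh18a1 (1.19, standard error 0.21). The list's median change was 0.36 (camera, adjusted p = 2.4e-09), and it did not pass with an estimated correlation (adjusted p = 0.0735). Leaving out 1 array ended the calls of Psph, Bcat1 and Aldh18a1, with limma adjusted p up to 0.0797, 0.260 and 0.253, each without ATF4 array 1.

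In one-carbon folate metabolism, 3 of 10 measured genes (16 listed) rose and 7 did not pass, with the same 3 when adjusted over the list alone. Each of the 3 is a mitochondrial enzyme. Aldh1l2 rose 5.42-fold from 6.17 ± 0.23 to 8.61 ± 0.19 (limma adjusted p = 0.000248), the serine hydroxymethyltransferase Shmt2 by 1.67 on the log2 scale (standard error 0.29) and the methylenetetrahydrofolate dehydrogenase Mthfd2 by 1.33 (0.23). Without ATF4 array 1 the limma adjusted p was 0.158 for Shmt2 and 0.192 for Mthfd2. The list's mean change was 0.45 and its median -0.03. Its camera call (adjusted p = 0.0103) ended with an estimated correlation (adjusted p = 0.419), with the replicate block (0.153) and under each of the 4 rescalings (0.0588 to 0.136).

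Amino acid transporters also rose. All 20 listed genes were measured, 6 rose, none fell and 14 did not pass (9 rose when adjusted over the list alone, 10 with the replicate block). The median change was 0.34 (camera, adjusted p = 1.8e-17, and 0.0328 with an estimated correlation). The call was lost with both the block and an estimated correlation (camera, adjusted p = 0.242), where 0 of the 30 lists passed. After Slc7a11, the glycine transporter Slc6a9 had the largest rise, from 6.21 ± 0.22 to 7.98 ± 0.28 (limma adjusted p = 0.00308). The cationic amino acid transporter Slc7a3 rose by 1.62 (standard error 0.23) and the large neutral amino acid transporter Slc7a5 by 1.45 (0.25). The limma adjusted p of Slc7a3 was 0.0564 without control array 1, and that of Slc7a5 was 0.191 without ATF4 array 1 and 0.0942 to 0.139 under the 4 rescalings.

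Cytosolic tRNA synthetases, the enzymes that charge tRNAs with amino acids, were higher as a list, with no single member past the threshold over all rows. Of 20 listed genes 16 were measured; 10 rose when adjusted over the list alone, and 10 with the replicate block over all rows. The median change was 0.66 (camera, adjusted p = 2.0e-15), but the call was lost with an estimated correlation (adjusted p = 0.255). Rars, which charges arginine, had 9.71 ± 0.38 in control and 10.78 ± 0.23 in ATF4 arrays (limma adjusted p = 0.0859, and 0.00682 with the block). Gars, which charges glycine, had a log2 change of 1.16 with a standard error of 0.26 (limma adjusted p = 0.101, and 0.00691 with the block). The 15 measured mitochondrial tRNA synthetases had a median of -0.08 and did not shift (camera, adjusted p = 0.854); Iars2 had -0.17 and Rars2 0.58 (limma adjusted p = 0.892, and 0.0471 with the block, the 1 member past the threshold there). Neither did 23 translation initiation and elongation factors (median 0.02; camera, adjusted p = 0.271), of which 0 passed without the block and 2 with it. Among these Eif2s2 had 0.85 (limma adjusted p = 0.295, and 0.0149 with the block) and Eif3c 0.57 (0.793 and 0.0380).

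Chaperones and degradation factors of the endoplasmic reticulum did not shift (25 of 27 listed genes measured, median 0.02; camera, adjusted p = 0.141). Over all rows 0 members passed without the replicate block and 2 with it; 1 rose when adjusted over the list alone. Dnajb9, a co-chaperone of the luminal Hsp70 protein, had 7.09 ± 1.11 in control and 9.53 ± 0.74 in ATF4 arrays (limma adjusted p = 0.0790, and 0.00284 with the block). Derl1, a channel of the degradation pathway, had a log2 change of 0.55 (0.434, and 0.0332 with the block). Mitochondrial chaperones and proteases were higher as a list of 11 measured genes (median 0.08; camera, adjusted p = 0.00179; adjusted p = 0.509 with an estimated correlation), with 0 members past the threshold over all rows, 3 with the block and 1 when adjusted over the list alone. Among them the protease Lonp1 had 0.81 (limma adjusted p = 0.204, and 0.0202 with the block) and Hspa9 0.64 (0.514 and 0.0353). Without control array 3 this list's adjusted p was 0.291.

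Among genes linked to muscle atrophy, Gadd45a, a growth arrest and stress gene, stood highest. It had 8.79 ± 0.14 in control and 9.65 ± 0.18 in ATF4 arrays, a 1.81-fold difference with no overlap between groups (transcript cluster 6954385; limma adjusted p = 0.0859, and 0.0155 with the replicate block). The ubiquitin ligase gene Fbxo32 had a log2 change of -0.17 (standard error 0.17) and the cell cycle inhibitor Cdkn1a -0.22 (0.22), both with a limma adjusted p of 1. The groups did not overlap for Fbxo32 either, and Trim63 had no named row. The autophagosome gene Map1lc3b had 0.39 (limma adjusted p = 1). Of 27 listed atrophy genes 23 were measured, none passed over all rows and 1, Gadd45a, rose when adjusted over the list alone, and with the block over all rows. The list's median was 0.12 (camera, adjusted p = 0.0103), but the call was lost with an estimated correlation (adjusted p = 0.337), without control array 3 (0.442) and under 3 of the 4 rescalings (up to 0.336). The 20 measured growth arrest and p53 target genes, of 22 listed, had a median of -0.10 and did not shift (camera, adjusted p = 0.979), although Sesn2 had 5.47 ± 0.33 in control and 6.67 ± 0.38 in ATF4 arrays (limma adjusted p = 0.0694, and 0.00451 with the block). In that list 0 genes passed over all rows, 3 rose when adjusted over the list alone, and with the block 3 rose and 1 fell.

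Cell cycle genes fell as a group. The 27 measured genes, of 31 listed, each had a lower mean in ATF4 arrays, with a median of -0.36 (camera, adjusted p = 7.0e-14; adjusted p = 0.0328 with an estimated correlation). No single gene passed over all rows or when adjusted over the list alone; with the replicate block 2 fell over all rows and 19 when adjusted over the list alone. These 2 were the cyclins Ccne1, with a change of -0.72 (standard error 0.19; limma adjusted p = 0.215, and 0.0350 with the block), and Ccnd1, with -0.59 (0.17; 0.269 and 0.0228). With both the block and an estimated correlation no list passed, this one included (adjusted p = 0.287).

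Sarcomere genes were lower as a list. Of 38 listed genes 25 were measured and 23 had a lower mean in ATF4 arrays, with a median of -0.30 (camera, adjusted p = 3.4e-07), but the call was lost with an estimated correlation (adjusted p = 0.501) and without ATF4 array 3 (0.0615). No gene passed over all rows or when adjusted over the list alone. With the replicate block 6 fell over all rows, and 18 fell and 1 rose when adjusted over the list alone. Among the 6 was the myosin-binding protein Mybpc2, with a change of -1.08 (standard error 0.32, limma adjusted p = 0.336, and 0.0161 with the block). The Z-disc gene Ldb3 had -0.46 (0.612, and 0.0501 with the block). Sarcomere genes also differed within groups: against the other arrays of the group, their median was -0.56 on control array 3 and -0.54 on ATF4 array 3. Bright rows in general were lower on both arrays. With the trend with brightness removed, the sarcomere median was -0.11 on control array 3 and -0.30 on ATF4 array 3. Calcium handling and excitation genes (19 of 20 listed genes measured) had a median of -0.17 (camera, adjusted p = 0.00606), lost with an estimated correlation (adjusted p = 0.337), without control array 1 (0.162) and without ATF4 array 3 (0.30). None of them passed over all rows or when adjusted over the list alone, and 3 fell with the block. Casq1, the calcium store protein calsequestrin, had -0.85 (limma adjusted p = 0.468, and 0.0194 with the block) and Stac3 -0.48 (0.517 and 0.0490). Myogenic regulators did not shift (20 measured, median -0.03; camera, adjusted p = 0.268). None passed, and 3 fell with the block; the repressor gene Msc had -0.53 (limma adjusted p = 0.517, and 0.0779 with the block) and the methyltransferase gene Smyd1 -0.53 (0.439 and 0.0394). Nor was there a shift of 17 neuromuscular junction and denervation genes (median -0.05; camera, adjusted p = 0.534). In that list 1 gene rose, also when adjusted over the list alone, and 2 with the block: the receptor kinase gene Musk rose from 7.62 ± 0.34 to 9.04 ± 0.33 (limma adjusted p = 0.0273, and 0.164 without ATF4 array 1), and Chrnd had 0.67 (0.532, and 0.0181 with the block).

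Interferon response genes were lower in ATF4 arrays. Of 33 listed genes 24 were measured and 23 had a lower mean, with a median of -0.79 (camera, adjusted p = 4.3e-27), but the call was lost with an estimated correlation (adjusted p = 0.0846). Irf7 fell, and 18 genes fell when adjusted over the list alone; with the replicate block 10 fell over all rows and 19 when adjusted over the list alone. The guanylate-binding protein Gbp3 had 6.83 ± 0.69 in control and 5.29 ± 0.07 in ATF4 arrays (limma adjusted p = 0.0584, and 0.0313 with the block). The list's median level was 6.78, 6.41 and 5.85 on control arrays 1 to 3 and 5.42, 5.54 and 5.43 on ATF4 arrays 1 to 3, so that the control arrays differed more among themselves than the ATF4 arrays. Inflammatory cytokines and NF-kB targets did not shift (19 measured, median -0.01; camera, adjusted p = 0.289), with Il1b at 0.74 (limma adjusted p = 0.214) and Il6 at -0.34 (1).

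**Figure D2:**
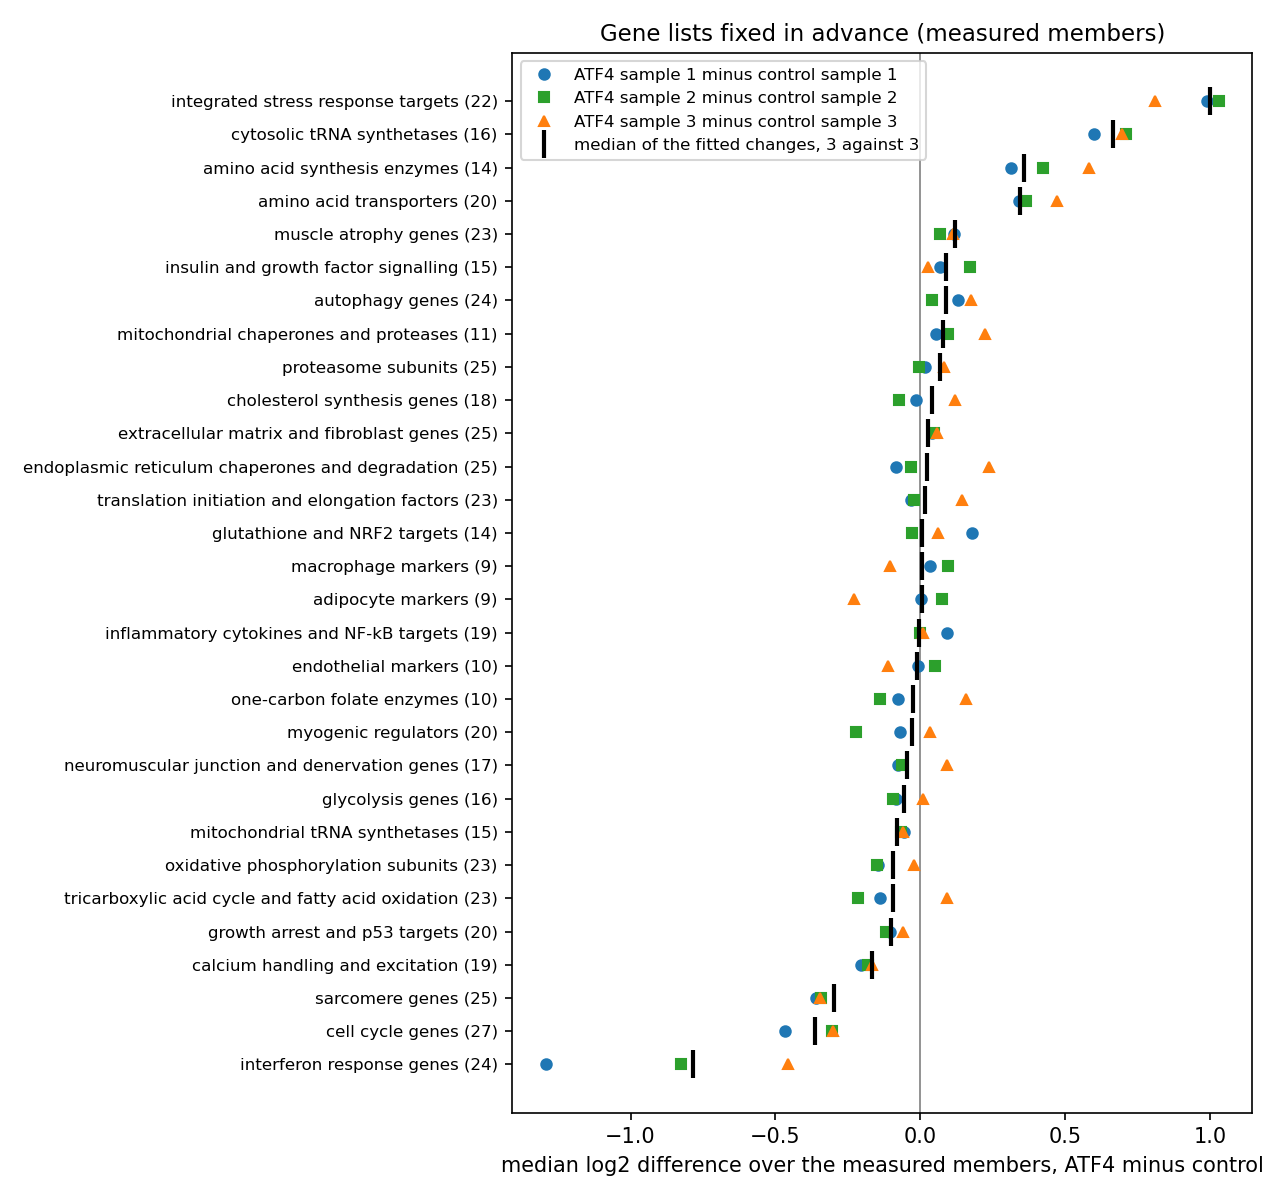
Median log2 difference, ATF4 minus control, over the measured members of each of 30 gene lists (horizontal axis); coloured points are differences between arrays of the same sample number and black bars the median of the fitted changes of 3 against 3 arrays. Integrated stress response targets lie at 0.99, 1.03 and 0.81 and interferon response genes at -1.29, -0.83 and -0.46 in the 3 pairs.

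Among metabolic and turnover lists, autophagy genes were higher (24 measured, median 0.09; camera, adjusted p = 0.00459), a call lost with an estimated correlation (adjusted p = 0.560), without control array 3 (0.807), without ATF4 array 1 (0.137) and without ATF4 array 2 (0.0541). No autophagy gene passed over all rows or when adjusted over the list alone; with the block 2 rose, Wipi2 with a change of 0.73 (limma adjusted p = 0.265, and 0.0178 with the block) and Atg4a with 0.54 (0.513 and 0.0464). Insulin and growth factor signalling genes missed the threshold (15 measured, median 0.09; camera, adjusted p = 0.0526) and passed with the replicate block (0.0125), but not with an estimated correlation, either without the block (adjusted p = 0.560) or with it (0.287). No member passed, and 2 rose with the block, the IGF-binding protein gene Igfbp5 with 0.64 (limma adjusted p = 0.513, and 0.0394 with the block) and Pik3r1 with 0.60 (0.664 and 0.0269). Oxidative phosphorylation subunits (23 measured, median -0.09; camera, adjusted p = 0.141) and tricarboxylic acid cycle and fatty acid oxidation genes (23 measured, median -0.09; 0.159) did not shift, although both were lower by camera under 3 of the 4 rescalings (adjusted p = 0.00370 and 0.0305 after quantile normalization). No member of either passed over all rows; when adjusted over the list alone, 1 oxidative phosphorylation gene rose and 1 fell. Within them the heart and muscle cytochrome oxidase subunits Cox8b and Cox6a2 differed in opposite directions, by -1.34 and 1.01 (limma adjusted p = 0.139 and 0.20, and 0.0139 and 0.0147 with the block), the fatty acid transporter Cd36 had -0.98 (0.343 and 0.0152) and Acaa2 -0.39 (1). Glycolysis genes did not shift (16 measured, median -0.06; camera, adjusted p = 0.717), and 0 passed over all rows, while 3 rose and 3 fell both with the block and when adjusted over the list alone. Among these were hexokinase Hk2 at 1.11 and the muscle phosphoglycerate mutase Pgam2 at -1.10 (limma adjusted p = 0.101 and 0.130, and 0.00451 and 0.0139 with the block). Glutathione and NRF2 target genes did not shift as a list (14 measured, median 0.01; camera, adjusted p = 0.15), but heme oxygenase, Hmox1, rose by 1.36 (standard error 0.23; limma adjusted p = 0.0303, and 0.192 without ATF4 array 1), while Gsta4 had -0.73 (0.729, and 0.0232 with the block). Proteasome subunits (25 measured, median 0.07; camera, adjusted p = 0.331; Psma3 -0.27, Psmc3 -0.21) and cholesterol synthesis genes (18 measured, median 0.04; 0.928; Mvd -0.37, Insig1 -0.25) did not shift.

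Markers of other cell types did not shift as lists by camera. The 9 measured macrophage markers had a median of 0.00 (adjusted p = 0.274; Cd14 0.79, Ptprc 0.75), the 10 endothelial markers -0.01 (0.979; Cdh5 0.41, Pecam1 -0.15), the 9 adipocyte markers 0.00 (0.578; Adipoq -0.35, Lpl -0.19) and the 25 extracellular matrix and fibroblast genes 0.03 (0.357; Mmp2 0.26, Pdgfra 0.21). No member of these 4 lists passed over all rows with or without the replicate block; when adjusted over the list alone, 1 macrophage marker was higher, and with the block 2 were higher and 1 lower. Ptprc passed over all rows with array weights (limma adjusted p = 0.00362), without control array 3 (0.0467), with cyclic loess and the block (0.0357) and with the block without the number 3 arrays (0.0352), against 0.222 as fitted. Cd14 passed with array weights (0.0318) and with the block without the number 3 arrays (0.0367), against 0.514.

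In all, 12 of the 30 lists passed by camera with the preset correlation, 8 higher and 4 lower. By that test 4 of the 10 splits of the arrays, the real one included, gave as many lists. The count alone therefore does not set the real groups apart. Of the 12 lists, 3 passed with an estimated correlation: the integrated stress response and transporter lists higher and the cell cycle list lower. With the block as well, 0 passed. With fry, 4 lists passed without the block (these 3 and the amino acid synthesis enzymes) and 10 with it. Of the 18 lists that did not pass, 10 passed by camera when 1 array was left out. Their lowest adjusted p was 0.00719 for translation factors, 0.00102 for endoplasmic reticulum chaperones, 0.0275 for neuromuscular junction genes and 0.00719 for insulin signalling, each without control array 1. It was 0.000388 for oxidative phosphorylation, 1.2e-05 for the tricarboxylic acid cycle list and 0.0343 for macrophage markers, each without control array 3. It was 0.0348 for myogenic regulators without ATF4 array 1, 0.0221 for extracellular matrix genes without ATF4 array 2 and 0.00571 for proteasome subunits without ATF4 array 3. Centring each array on its median ended the calls of Bcat1, Aldh18a1, Shmt2, Mthfd2, Hmox1 and Musk (limma adjusted p from 0.110 to 0.166), and scaling to one interquartile range those of Bcat1 (0.0792), Aldh18a1 (0.0554) and Hmox1 (0.0707). The number 3 arrays of both groups stood apart from the other 4 on the first principal component, which held 54.7% of the variance, and the groups separated on the second, with 22.7%. Without both number 3 arrays, a setting chosen after seeing the data, 157 rows passed, 123 higher and 34 lower.

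**Figure D3:**
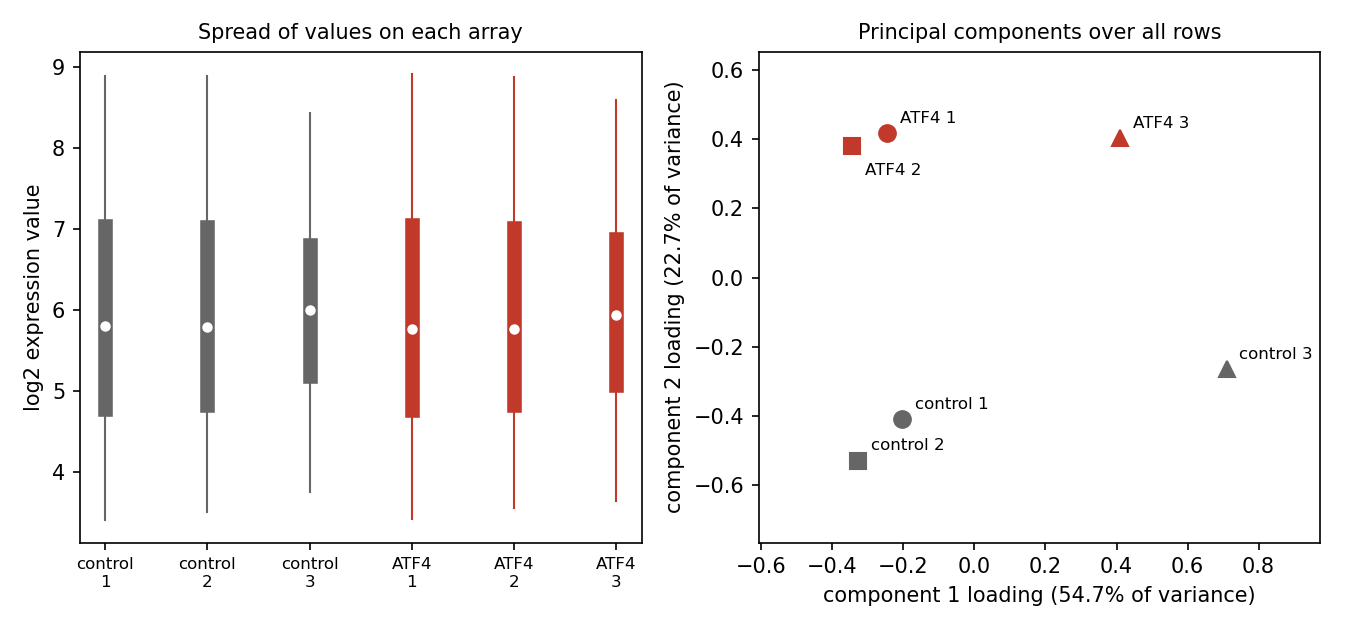
Left, log2 expression values on each array (white point, median; thick line, 25th to 75th percentile; thin line, 5th to 95th percentile); right, loadings of the 6 arrays on the first and second principal components over all rows. The interquartile range was 1.63 on control array 3 and 1.80 on ATF4 array 3, against 2.19 to 2.28 on the other 4 arrays.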

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

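Leaving out both number 3 arrays, leaving out a numbered pair under the block, cyclic loess and the block with an estimated correlation were chosen after seeing the data. No called result reversed under any of these settings. Against 99 rows, the replicate block gave 594, and 261, 354 and 630 with the number 3, number 1 or number 2 arrays left out; array weights gave 561, cyclic loess 151 (616 with the block), leaving out both number 3 arrays 157, centring on the median 57 and a threshold of 0.01 gave 41. With 1 array left out the count ran from 38 (without ATF4 array 1) to 243 (without control array 3), with 49 without control array 1 and 44 without ATF4 array 2. The other settings gave 76 to 133. The share of higher rows, 96.0%, was 67.3% with the block, 63.6% with array weights and 61.3% without control array 3. Against 12 lists, an estimated correlation gave 3, fry 4 and the replicate block with an estimated correlation 0; the other settings gave 11 to 16, that range including each array left out. With the block alone, 12 lists passed: one-carbon folate enzymes were lost and insulin and growth factor signalling gained. Over 81 named genes, 1510 values kept their side of the threshold, 173 passed only under the alternative and 75 passed only as reported; for lists these were 572, 36 and 51. With each array left out in turn, 16 of 29 called genes and 6 of 12 called lists kept their call throughout. For named genes over all rows and for lists by camera with the preset correlation, the block changed no call beyond those given with it. Counts adjusted over a list alone also moved with the block, and not all of these are given. Examples are myogenic regulators, from 0 to 5 lower, and endoplasmic reticulum chaperones, from 1 to 4 higher. The macrophage list had no member left above the median of rows and has no value there. Apart from fewer arrays, rows or a stricter threshold where the setting has them, the cause was not tested. Signal over background could not be judged without detection calls, which limits what dim rows can show.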

Other observations

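The tests of the number 3 arrays, of the interferon response genes and of macrophages and endothelial cells, and the count of lists over splits that part every pair, were chosen after the result was seen; the test of neighbouring genes and the other counts of splits were set before. The genes in the next paragraphs were chosen after their values were seen.

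These genes stand outside the lists and were not tested as a group. Pla2g2e, a secreted phospholipase, rose 4.18-fold from 6.40 ± 0.47 to 8.47 ± 0.13 (n = 3; limma adjusted p = 0.00286). Gfral, the receptor of the stress hormone GDF15, rose from 4.39 ± 0.24 to 6.25 ± 0.25 (limma adjusted p = 0.00205), and the secreted Wnt antagonist gene Sfrp4 from 6.74 ± 0.25 to 8.54 ± 0.17 (limma adjusted p = 0.00205). The elastic fibre gene Fbln5 rose 3.16-fold and the surface sialomucin gene Cd34 2.69-fold, both with a limma adjusted p of 0.00495. Cd93, dim in control arrays (3.61), rose by 1.92 on the log2 scale, the cation channel gene Trpc1 by 1.92, the lysophosphatidic acid receptor gene Lpar4 by 1.82 and the transcription factor gene Etv5 by 1.47. They were picked from rows that passed with the replicate block and whose groups did not overlap. Passing with the block and being higher in 3 of 3 pairs therefore follow from the choice and add no support.

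Some genes outside the lists fell with the replicate block and did not pass without it. They too were not tested as a group. These genes were also picked from rows that passed with the block and whose groups did not overlap. Passing with the block therefore follows from the choice and adds no support. The sarcoplasmic reticulum gene Hrc had a log2 change of -0.98 (limma adjusted p = 0.00629 with the block, and 0.174 without). The Z-line gene Pdlim3 had 8.52 ± 0.41 in control and 7.43 ± 0.48 in ATF4 arrays (0.00451 and 0.190), and the sarcoplasmic reticulum gene Dhrs7c 7.56 ± 0.33 and 6.66 ± 0.21 (0.0203 and 0.143). The guanylate-binding protein gene Gbp7 had a change of -1.36 (0.0233 and 0.0881), Dtx3l -1.02 (0.0478 and 0.221) and the lipocalin gene Apod -1.11 (0.00535 and 0.144).

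The number 3 arrays of both groups stood apart from the other arrays of their groups. A narrower signal range on them is a candidate explanation. Regressed on the mean of the other arrays of the group, they had slopes of 0.809 (control) and 0.876 (ATF4), against 1.02 to 1.10 for the other 4 arrays. The mean used for each of those 4 held its group's number 3 array, which raises their slopes. Interquartile ranges, which share no such reference, were 1.63 (control) and 1.80 (ATF4) on the number 3 arrays and 2.19 to 2.28 on the other 4. The dimmest 10% of rows was higher on the number 3 arrays (by 0.33 and 0.19) and the brightest 10% lower (-0.50 and -0.30), and this trend held 48.6% and 38.3% of the variance of their deviations. Less mature myotubes in these cultures cannot be told apart from it for both arrays: with the trend removed, the sarcomere median lay at percentile 10.05 of 10000 brightness-matched random lists on control array 3 and at 0.01 on ATF4 array 3. What the sample numbers stand for is not given, and no other biological difference between them was tested.

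The interferon response genes were lower in ATF4 arrays in each pair. The number 3 arrays are not the source, since the list's median change was -1.03 without them. A lower virus load in the ATF4 cultures may contribute and cannot be told apart from an effect of ATF4. The Atf4 row, with sequence in both vectors, changed by -0.0382 with a standard error of 0.26. Any ATF4-dependent change of the cells' own Atf4 transcript would also enter that value, and it was not measured apart from the vectors. Nor is it known how many probes of the row lie in the bZIP part that the control vector lacks, so equal virus loads need not give equal values. That ATF4 activity lowers these genes stays a hypothesis, because the virus load of the cultures is not known. The list also missed the threshold by camera with an estimated correlation, without the block (adjusted p = 0.0846) and with it (0.414). With the block 0 of the 30 lists passed in that setting.

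Among the 12 largest rises of named genes past the threshold, signal spread from neighbouring genes was not seen: 0 of the 12 had a measured next neighbour that rose by at least 0.5 times as much. Over 19 macrophage and endothelial markers the median change was 0.00 and the 90th percentile 0.479, which argues against a general rise of these 19. It does not cover blood or vessel cell genes outside the 19. Among genes named above, Plek, Cd34 and Cd93 rose and Cd28 fell. The cultures were of a myoblast line, so macrophages or endothelial cells could only be contaminants. The markers do not settle whether there were any, since Cd14 reached 1.09 without the number 3 arrays. That is above 1.06, which is 0.5 times the smallest of the 12 rises and a limit assumed after seeing the values. Other cell types, and binding of labelled RNA from another gene to the same probes, were not tested.

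Splits of the 6 arrays into other groups of 3 are too few (10) for a share under 0.05. The real split gave 99 rows and the highest of the others 2, so 1 of the 10 splits gave as many. For lists by camera with the preset correlation, the real split gave 12 and the highest of the others 19, and 4 of the 10 splits gave as many. The 6 splits that part only 1 pair of arrays of the same number gave 18, 11, 6, 10, 19 and 12 lists, and these include the 3 others with as many. The 4 splits that part every pair, as the real one does, gave 12 lists for the real one and 6, 11 and 6 for the others, so 1 of the 4 gave as many; these are too few as well. With the replicate block, 4 splits part every pair, also too few. The real one gave 594 rows and the highest of the others 0, so 1 of the 4 gave as many. Every other split puts arrays of both groups on each side. A real difference between the groups then adds to the spread and can lower the count of rows. The few rows of the other splits therefore do not show what chance alone would give.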
